A study of Mus musculus with 7 samples.

How the data were processed

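The ventrolateral ventromedial hypothalamus was dissected by hand from 7 ovariectomized female mice of mixed background with 129/Sv ancestry, 4 hours after a subcutaneous injection of vehicle (3 mice) or 1 µg of estradiol benzoate (4 mice). Libraries were made from 15 ng of RNA with a Tecan/NuGEN Trio kit, per the labels' protocols. The authors deposited raw counts per gene for each library, whole numbers for 48321 genes with no normalisation. Reads were aligned with HISAT2 and counted with HTSeq against mm10, and DESeq2 was used, per the submitters' processing notes. Tool versions, the annotation, the handling of multiply mapped reads and the use of strand are not given in the sources used here. Library totals ran from 21037303 to 33302293 counts, and 23668 to 25901 genes had at least 1 count in a library.

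Replicate pairs within a group were compared by chi-square over genes, and their statistic per degree of freedom ran from 18.6 to 185, so that no pair differed by less than sampling noise. Each library is a separate mouse, and replicate numbers here only name the mice of a group, in the order of their deposited samples. No paired analysis was possible because the labels give no shared replicate numbers.

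Genes were kept by filterByExpr with a minimum count of 10, which left 18387 of 31222 genes with any count. Counts were scaled by TMM and tested with edgeR 4.0.16 (estimateDisp, glmQLFit with robust fitting, glmQLFTest) in R 4.3.3, with no covariate. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes, and every adjusted p for a gene is from this test unless another tool is named. Standard errors of log2 changes were taken as the absolute change over the square root of the F statistic. CPM values are TMM-normalised, given as mean ± SD over mice. The biological coefficient of variation was 22.3%.

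The 33 gene lists, the named-gene rule, the main test and 18 sets of alternatives were chosen before the data were examined. The lists cover estrogen receptor targets, steroid receptors and coregulators, the melanocortin system, VMH and VMHvl neurons, neuropeptides and their receptors, immediate early, glucocorticoid response, clock, unfolded protein response, potassium channel, glutamate and GABA receptor and energy and insulin genes. The others hold markers of neighbouring brain regions, glia, vessels, pituitary and blood, and strain-variable, sex-linked and mitochondrially encoded genes. Each list was tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry (limma 3.58.1), adjusted over the 33 lists. Calls were also counted after adjustment over the list alone.

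Genes were named by 3 parts of a rule, which gave 53 genes. The first part took the 10 largest increases and the 10 largest decreases among changed genes with a mean CPM of at least 1 in a group, no overlap between groups and a symbol that is not a predicted model. The next took up to 4 members per list called over all genes or over the list alone, by smallest p. The last always took Mc4r, Mc3r, Esr1, Esr2, Pgr, Greb1, Nmur2, Pomc, Agrp and Nr5a1. A set of 8 lists was added after the results were seen: interferon-stimulated genes, cell division genes, synaptic adhesion and axon guidance, aminergic receptors, RGS proteins, cholesterol synthesis, glycan sulphation and sialylation enzymes, and TRPC channels. Tests of these added lists were adjusted over those 8 lists only.

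Alternatives were DESeq2 1.42.0, limma-voom with and without sample weights, 2 other quasi-likelihood fits, 3 other scalings, 2 other filters, removal of mitochondrial and haemoglobin genes, 1 surrogate variable (sva 3.50.0), an arcuate marker covariate, an adjusted p under 0.1, a test against a 1.2-fold change, and each library left out in turn. Those added after seeing the data removed rRNA genes, removed vehicle 1 and EB 4 together, used fibroblast or endothelial marker covariates, and repeated the list tests without each library. Composition measures were compared by two-sided exact permutation over 35 splits.

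The tests were checked on 5 simulations of the EB and vehicle comparison with 200 changed genes each, over a mean of 17738 tested genes. EdgeR recovered 31.6% of genes changed 1.5-fold, 53.7% of those changed 2-fold and 83.9% of those changed 4-fold, and 10.0% of its calls were false. False calls made up 20.5% of DESeq2 calls and 6.32% of limma-voom calls. Positions were taken from GENCODE annotation of GRCm38, the assembly also named mm10, with 98.3% of tested symbols matched and 174 of the 175 changed genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.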

Results

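RNA was sequenced from the ventrolateral part of the ventromedial hypothalamus (VMHvl), a region rich in estrogen receptor alpha neurons, of ovariectomized female mice. Ovariectomy removes the main source of circulating estrogen. Mice received vehicle (3 mice) or 1 µg of estradiol benzoate (EB, 4 mice), an ester of estradiol, and tissue was taken 4 hours later. Each library came from a single mouse, so replicate error here is variation between animals. Library totals were 29968437, 30909554 and 21037303 counts for vehicle 1 to 3, and 33302293, 32250181, 22791948 and 22311424 counts for EB 1 to 4. The comparison of EB with vehicle asks which VMHvl transcripts differ 4 hours after estrogen replacement, and the series title names melanocortin signalling and spontaneous activity as its subject.

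The gene with the largest change was Zbtb42, a BTB zinc-finger transcription factor, which rose from 0.163 ± 0.0112 CPM (TMM-normalised counts scaled to library size) with vehicle (SD, n = 3) to 15.4 ± 5.24 CPM with EB (SD, n = 4). Its log2 fold change was 6.52 ± 0.43 (SE), from 4 to 5 counts in each vehicle library to 305 to 539 in each EB library. Iigp1, an interferon-inducible GTPase, rose 24.9-fold (log2 4.64 ± 0.48), and Phf21b, a PHD-finger protein, rose 15.5-fold (3.96 ± 0.23). Gpr6, an orphan G-protein-coupled receptor with high constitutive activity, rose 8.36-fold. Mad2l1, a protein of the spindle assembly checkpoint, rose 7.65-fold, and Gadd45a, a stress-inducible growth arrest gene, rose 7.43-fold. The other genes named by size of increase were Arhgef38 (log2 3.02), Fam90a1b (2.75), Smim3 (1.88) and Chst15, a chondroitin sulphate sulphotransferase (1.78). Arhgef38 had 3 to 8 counts in each vehicle library. It was not called by limma-voom (adjusted p = 0.0592, and 0.0607 with sample weights) or without vehicle 1 and EB 4 together (0.0645). In all, 175 of 18387 tested genes differed, 137 higher and 38 lower with EB, by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p below 0.05. The groups did not overlap in any of the 175, whereas 9.10% of tested genes had no overlap and chance gives 5.71%. With 3 against 4 mice a call nearly requires separate groups, so this is not independent support. The median log2 change was 0.81 among the higher genes and −0.64 among the lower ones, and 47 rose and 8 fell by at least 2-fold. Leaving out vehicle 3 gave 78 higher and 24 lower genes, leaving out EB 1 gave 87 and 20, and leaving out EB 2 gave 107 and 24, while DESeq2 gave 234 and 125. Iigp1 lost its call without vehicle 2 (log2 4.49, adjusted p = 0.123) and Chst15 without vehicle 2 or vehicle 3 (adjusted p = 0.169 and 0.133). The division of reads between Iigp1 and its paralog Gm4951 is uncertain.

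**Figure D1:**
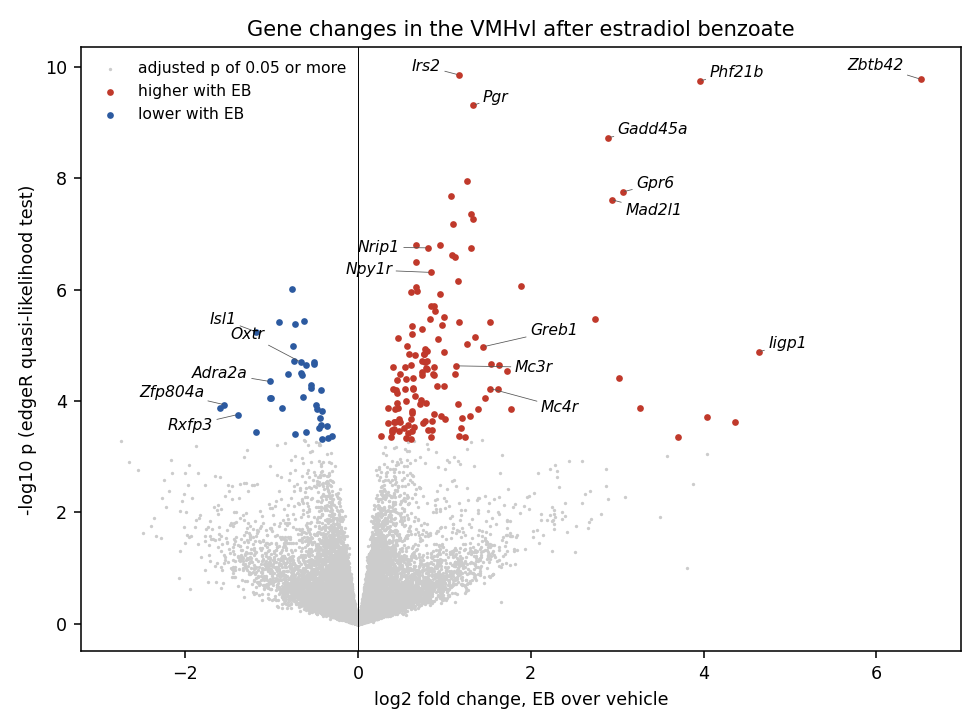
Each point is 1 of 18387 genes, with the log2 fold change of EB over vehicle on the horizontal axis and −log10 of the unadjusted p on the vertical axis; red points are the 137 genes higher and blue points the 38 genes lower with EB at an adjusted p below 0.05. Zbtb42 lies farthest to the right at 6.52, and Irs2 and Pgr have small p-values at changes of 1.16 and 1.34.

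Isl1, Rxfp3, Adra2a and Htr1a were among the 38 genes that fell. Isl1, a LIM-homeodomain transcription factor, fell from 67.3 ± 18.2 to 29.7 ± 3.79 CPM (log2 −1.18 ± 0.16, adjusted p = 0.00249). Rxfp3, the relaxin-3 receptor, changed by −1.39 ± 0.22, Adra2a, the alpha-2A adrenergic receptor, by −1.02 ± 0.17, and Htr1a, a serotonin receptor, by −0.92 ± 0.12 on the log2 scale. The zinc-finger gene Zfp804a fell from 122 ± 32.5 to 41.8 ± 10.4 CPM, and the orphan nuclear receptor Nr2f1, also called COUP-TFI, from 27.5 ± 1.96 to 15.7 ± 2.37 CPM. Popdc3 (log2 −1.60), Setdb2 (−1.18), Slc40a1, the iron exporter ferroportin (−1.02), and Tmem74 (−0.88) completed the 10 genes named by size of decrease. Vehicle 2 had the highest vehicle CPM in each of these 10. It stood at 87.8 for Isl1 against 53.3 and 60.7 in vehicle 1 and 3, and at 100 for Rxfp3 against 51.3 and 59.1. For Nr2f1 it was 28.63 against 28.61 in vehicle 1. With any 1 library left out, the smallest log2 decrease was −0.94 for Isl1, −1.04 for Rxfp3 and −0.72 for Adra2a. Isl1, Adra2a, Htr1a and Nr2f1 were called without each library in turn. Without 1 library the adjusted p reached 0.130 for Rxfp3 (EB 1), 0.112 for Popdc3 (vehicle 2), 0.232 for Setdb2 (vehicle 2), 0.0963 for Tmem74 (EB 1), 0.0890 for Zfp804a (EB 1) and 0.0686 for Slc40a1 (vehicle 2). Calls were also lost without EB 2 or EB 4 for Rxfp3, Zfp804a, Setdb2 and Tmem74 and without EB 2 for Popdc3. Removing vehicle 3 ended the calls of Setdb2, Tmem74 and Slc40a1, removing vehicle 2 that of Tmem74 and removing EB 1 those of Popdc3, Setdb2 and Slc40a1.

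Textbook estrogen receptor targets were among the called genes. Pgr, the progesterone receptor, rose from 82.2 ± 6.70 to 207 ± 17.6 CPM (2.52-fold, log2 1.34 ± 0.09, adjusted p = 2.26e-06), Greb1, an estrogen-induced coactivator, rose 2.73-fold, Nrip1, a corepressor of nuclear receptors, 1.75-fold, and Cckar, the cholecystokinin A receptor, 2.61-fold. Oxtr, the oxytocin receptor, fell from 118 ± 14.7 to 74.6 ± 8.50 CPM (log2 −0.66 ± 0.10). Of 26 measured members of the list, 4 were higher, 1 was lower and 21 were not called, against 7 higher and 3 lower when adjusted over the list alone. The list ranked higher as a set (camera, adjusted p = 0.000277 over 33 lists; adjusted p = 0.159 with an estimated correlation), with a median log2 change of 0.08. Fry, which tests whether the members moved on balance one way and does not set them against other genes, gave an upward direction (adjusted p = 0.0364). Cckar lost its call without vehicle 3 (adjusted p = 0.133), EB 1 (0.0752), EB 3 (0.0624) or EB 4 (0.0722).

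The receptors through which estradiol acts did not pass the test. Esr1, estrogen receptor alpha, was at 223 ± 81.6 CPM with vehicle and 192 ± 30.2 CPM with EB (log2 −0.21 ± 0.25, adjusted p = 0.892), and Esr2 was at 7.07 ± 3.13 and 5.48 ± 1.95 CPM (log2 −0.41). Both point estimates turned positive without vehicle 2, to 0.13 and 0.040. Among 22 steroid receptor and coregulator genes, Pgr, Nrip1 and Fkbp5, a cochaperone of the glucocorticoid receptor (log2 0.88 ± 0.17), rose and Nr3c1, the glucocorticoid receptor itself, fell from 181 ± 4.58 to 141 ± 11.3 CPM. Adjusted over the list alone 3 were higher and 4 lower. The set test gave an adjusted p of 0.276 (0.0496 without vehicle 2), and its direction and mean (0.01) were upward while the median was −0.07. Fkbp5 lost its call without vehicle 1, 2 or 3 or EB 1 (adjusted p = 0.0688, 0.141, 0.133 and 0.0630) and Nr3c1 without vehicle 1 or 3 or EB 1, 3 or 4 (0.0941, 0.161, 0.106, 0.0850 and 0.0929).

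The neuronal melanocortin receptor genes Mc4r and Mc3r rose with EB. Mc4r, the melanocortin 4 receptor, went from 6.50 ± 0.903 to 18.8 ± 7.11 CPM (2.89-fold, log2 1.53 ± 0.26, adjusted p = 0.0112), and Mc3r, the melanocortin 3 receptor, from 8.63 ± 1.53 to 18.8 ± 3.54 CPM (2.20-fold, log2 1.14 ± 0.18, adjusted p = 0.00613). Pomc, the precursor of the melanocortin agonists, was at 18.1 ± 4.73 and 28.6 ± 9.48 CPM (adjusted p = 0.543), and Agrp, the melanocortin antagonist, at 0.632 ± 0.336 and 1.39 ± 0.803 CPM (adjusted p = 0.620). The 19 measured genes of the melanocortin list held 2 called genes, both higher, also when adjusted over the list alone, and the set test missed the threshold (camera, adjusted p = 0.0740; adjusted p = 0.709 with an estimated correlation) but passed it without EB 3 (adjusted p = 0.0184). The list was drawn up knowing the series title, so it is not an unguided choice. Mc3r kept its call without each library in turn, whereas Mc4r lost it without vehicle 1 (adjusted p = 0.0529), vehicle 2 (0.0975) or vehicle 3 (0.0893), with a log2 change between 1.24 and 1.66 when any 1 library was left out.

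**Figure D2:**
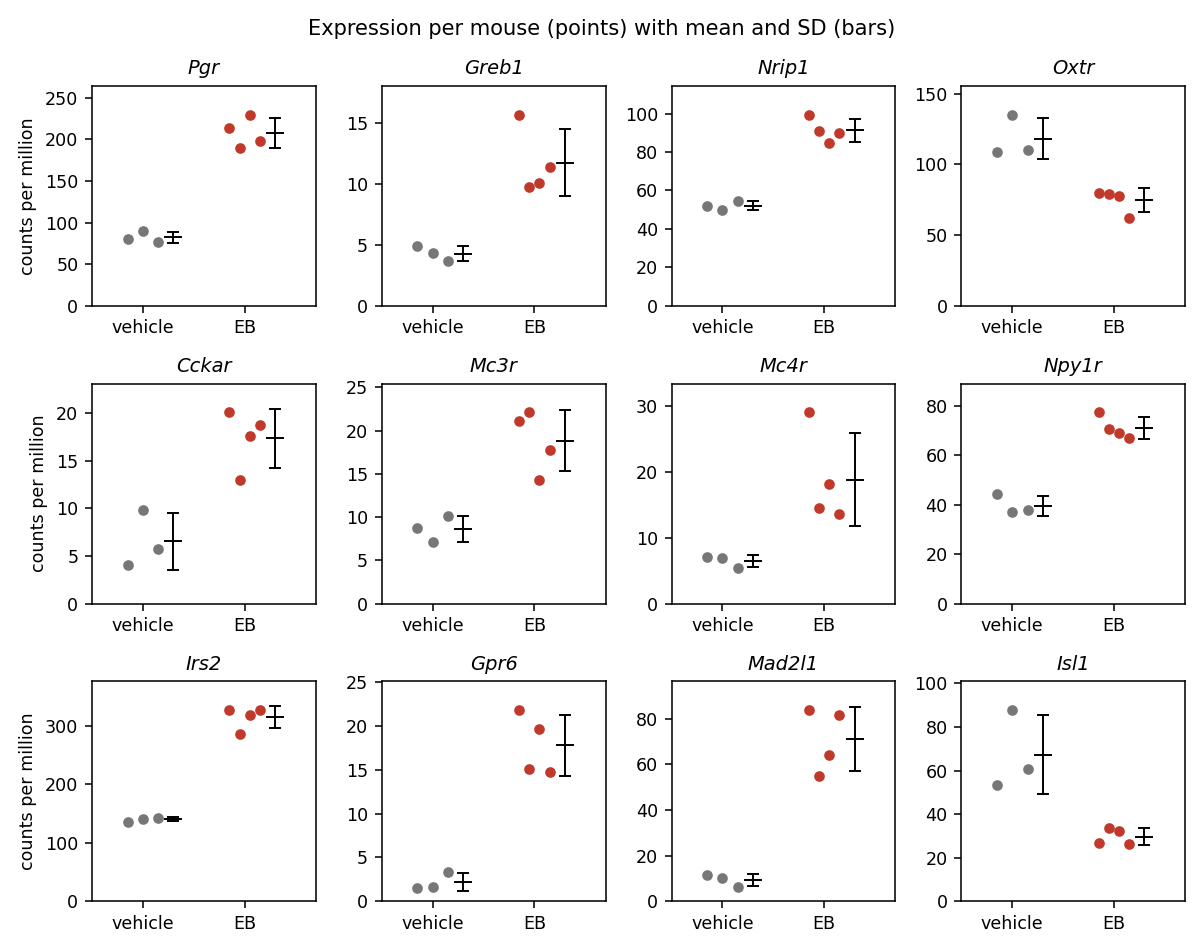
CPM of 12 genes in each mouse (grey, 3 vehicle; red, 4 EB), with the group mean and SD as black bars beside the points and each vertical axis starting at 0. The EB mice lie above all vehicle mice for Pgr, Greb1, Nrip1, Cckar, Mc3r, Mc4r, Npy1r, Irs2, Gpr6 and Mad2l1 and below them for Oxtr and Isl1.

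Neuropeptide receptors changed in both directions. Of 37 measured, 5 rose and 2 fell, and 30 were not called; adjusted over the list alone 7 were higher and 5 lower. Npy1r, a neuropeptide Y receptor, rose from 39.5 ± 3.98 to 70.9 ± 4.47 CPM (log2 0.84 ± 0.09), and Oprl1, the nociceptin receptor, from 104 ± 7.46 to 152 ± 15.2 CPM (0.54 ± 0.09), beside Cckar, Mc3r and Mc4r. Oprk1, the kappa opioid receptor, chosen after its values were seen, fell together with Oxtr (log2 −0.73 ± 0.15). Nmur2, the neuromedin U receptor 2, was at 25.5 ± 4.32 and 40.3 ± 7.83 CPM and did not pass over all genes (log2 0.66 ± 0.16, adjusted p = 0.0951) but did over the list alone. DESeq2 gave an adjusted p of 0.00333 and edgeR without EB 4 gave 0.0180. Ghsr, the ghrelin receptor, had a log2 change of −0.61 (adjusted p = 0.157, and 0.0160 without vehicle 3). The set test for the receptors gave an adjusted p of 0.0786, and 0.0184 and 0.0379 without EB 3 or EB 4. Of 32 measured neuropeptide genes edgeR called 0 over all genes or over the list alone (7 at an unadjusted p under 0.05, 1 by DESeq2, 0 by limma-voom; set test adjusted p = 0.382). Oprl1 lost its call without vehicle 3 (adjusted p = 0.0577), and Oprk1 without vehicle 2 or 3 (0.239 and 0.184) or EB 1, 3 or 4 (0.181, 0.0778 and 0.154).

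Immediate early genes, which neurons transcribe soon after stimulation, had mostly positive changes. Nptx2, neuronal pentraxin 2, rose 2.25-fold, Gadd45g 2.17-fold and Dusp1, a MAP kinase phosphatase, 2.01-fold, so edgeR called 3 of 30 measured members higher and 0 lower over all genes, against 9 higher and 1 lower when adjusted over the list alone. At an unadjusted p under 0.05 there were 12, and DESeq2 called 9 and limma-voom 3. Fos was at 1.53 ± 0.452 and 3.63 ± 0.254 CPM (log2 1.27 ± 0.29, adjusted p = 0.0682, and 0.00771 by DESeq2). Jun, chosen after its values were seen, had a log2 change of −0.36 and was called by DESeq2 but not by edgeR over all genes. The list had a median log2 change of 0.38 with 23 of 30 members positive, and ranked higher as a set (camera, adjusted p = 1.72e-05; adjusted p = 0.341 with an estimated correlation). Dusp1 held its call without vehicle 3 only, with an adjusted p of 0.0574 and 0.0664 without vehicle 1 and 2 and of 0.123, 0.0639, 0.0645 and 0.0576 without EB 1 to 4.

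Genes of insulin, glucocorticoid and clock pathways gave few calls. Irs2, an adaptor of the insulin receptor, rose from 140 ± 3.51 to 314 ± 19.0 CPM (2.24-fold, log2 1.16 ± 0.07, adjusted p = 1.09e-06) and was the 1 called gene among 24 of the energy and insulin list, which ranked higher as a set (camera, adjusted p = 0.0405; adjusted p = 0.709 with an estimated correlation). That set call ended without vehicle 1 (0.0963), vehicle 3 (0.148), EB 1 (0.0541) or EB 4 (0.197). The clock genes Npas2 (log2 0.75 ± 0.15) and Nfil3 (1.19 ± 0.25) rose among 19 measured, and adjusted over the list alone 4 were higher and 2 lower, among them Cry2 (0.48, adjusted p = 0.0434 over all genes without vehicle 2) and Rorb (−0.31). The set test gave an adjusted p of 0.820, with a mean of 0.06 and a median of −0.03. Fkbp5 was the 1 called gene of 18 glucocorticoid response genes, and Klf9 (log2 0.31 ± 0.07, adjusted p = 0.0628) passed over the list alone. Set direction was upward while the median was −0.10 and the mean −0.01 (adjusted p = 0.897). Npas2 and Nfil3 both lost their calls without vehicle 1 (adjusted p = 0.120 and 0.134), vehicle 3 (0.169 and 0.179), EB 1 (0.0837 and 0.149), EB 3 (0.0949 and 0.0655) and EB 4 (0.0929 and 0.0801). DESeq2 called 4 clock and 2 glucocorticoid response genes, and limma-voom 0 of either list. By limma-voom the adjusted p was 0.0584 for Fkbp5, 0.0661 for Npas2 and 0.0825 for Nfil3.

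Glutamate and GABA receptor genes and potassium channel genes gave no single calls by edgeR. Of 38 glutamate and GABA receptor genes 29 had negative changes (median −0.07), and the list ranked lower as a set (camera, adjusted p = 0.0108; adjusted p = 0.723 with an estimated correlation). EdgeR called 0 of the 38 (5 at an unadjusted p under 0.05; DESeq2 called 1, Gabra4, chosen after its values were seen; limma-voom 0). It also called 0 of 37 potassium channel genes (6 at an unadjusted p under 0.05; DESeq2 1, limma-voom 0; set test adjusted p = 0.143) and 0 of 20 unfolded protein response genes (2 at an unadjusted p under 0.05; DESeq2 1, limma-voom 0). The unfolded protein response set was downward by camera (adjusted p = 0.925), with a median of 0.00 and a mean of 0.01. The glutamate and GABA receptor call ended without vehicle 2 (adjusted p = 0.0716), vehicle 3 (0.0699) or EB 4 (0.0600).

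**Figure D3:**
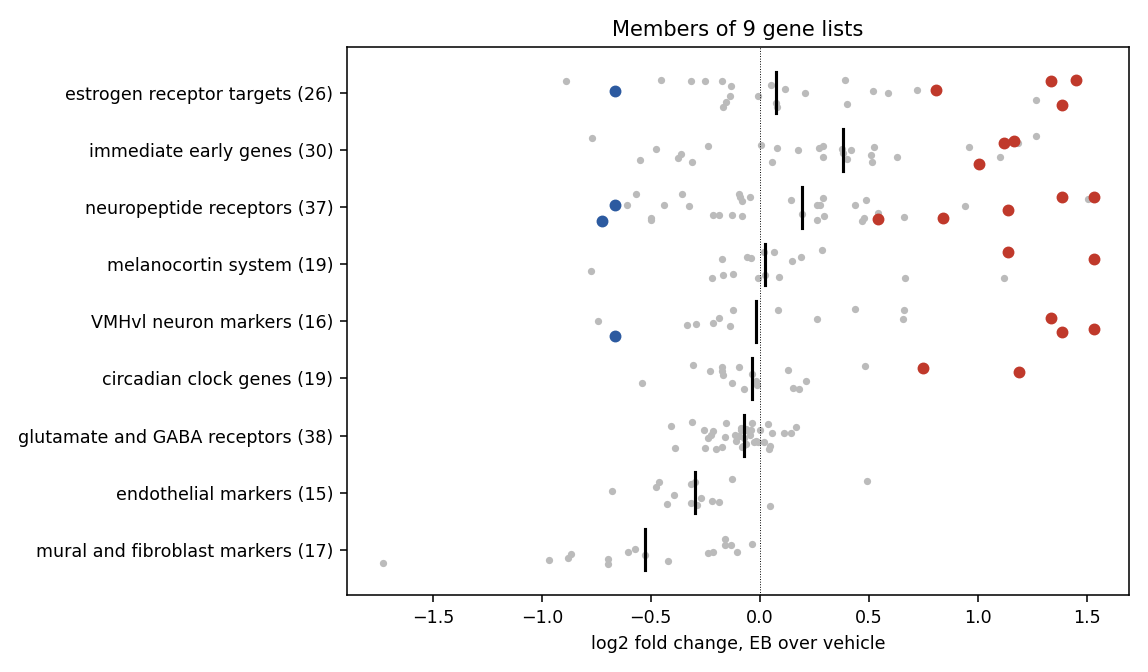
Log2 fold change of EB over vehicle for each measured member of 9 gene lists (number of members in brackets), with called genes in red (higher) or blue (lower), other genes in grey and the list median as a black line. Immediate early genes have a median of 0.38, and mural and fibroblast markers a median of −0.53 with no called member.

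VMHvl marker genes were affected through the receptors already named. Of 16 measured, Pgr, Mc4r and Cckar rose and Oxtr fell. Nmur2 and Rprm (log2 −0.74), the latter chosen after its value was seen, passed over the list alone, giving 4 higher and 2 lower. Nmur2 also passed over all genes by DESeq2 (adjusted p = 0.00333) and without EB 4 (0.0180). The set test was upward (camera, adjusted p = 0.0472; adjusted p = 0.709 with an estimated correlation) while the median was −0.02 and the mean 0.23. Its call ended without vehicle 1 (0.589), vehicle 3 (0.269) or EB 1 (0.0902). For the VMH as a whole, Nptx2 was the 1 called gene among 15, and Slc17a6, the vesicular glutamate transporter of VMH neurons, passed over the list alone (499.6 ± 61.3 and 633 ± 55.6 CPM, adjusted p = 0.111 over all genes, and 0.0401 without vehicle 2). The set test gave an adjusted p of 0.998 and a downward direction, with a median of −0.13 and a mean of 0.02. Mixed fry gave the VMH list an adjusted p of 0.000282. Nr5a1, a transcription factor of the adult VMH, was at 2.03 ± 1.02 and 2.52 ± 1.11 CPM (adjusted p = 0.881).

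Markers of neighbouring regions and other cell types gave 1 call by edgeR over all genes, Isl1, which belongs to the arcuate neuron list (14 measured, set test adjusted p = 0.932). Mixed fry gave the arcuate list an adjusted p of 0.0180. Endothelial markers were lower as a set (13 of 15 negative, median log2 −0.30; camera, adjusted p = 0.00602; adjusted p = 0.709 with an estimated correlation), with Flt1 (−0.48) and Abcb1a (−0.68; 0.0346 over all genes without EB 4) passing over the list alone. DESeq2 also called Flt1 (adjusted p = 0.0248), Abcb1a (0.0337), Ghsr of the arcuate list (0.0193), Slc17a6 of the thalamus list (0.0134) and P2ry12 of the microglia list (0.0169) over all genes. Markers from amygdala, striatum and cortex were lower in 12 of 14 (median −0.16; camera, adjusted p = 0.0472; adjusted p = 0.709 with an estimated correlation). All 17 mural and fibroblast markers had negative estimates (median −0.53), with 0 members called by edgeR, DESeq2 or limma-voom and 0 at an unadjusted p under 0.05. The set test gave an adjusted p of 0.143, and 0.000251 without vehicle 2 and 0.0121 without EB 4. Vehicle 1 stood highest in these markers, 1.39 log2 units above the mean of the 7 libraries, against −0.92 in EB 1, and EB 4 stood 1.07 above it in pituitary markers. The endothelial call ended without vehicle 1 (adjusted p = 0.330), and the regional one without vehicle 2 (0.139), vehicle 3 (0.148), EB 1 (0.0999) or EB 4 (0.258).

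By camera, which looks for a shift in 1 direction, set tests for the other marker lists missed the threshold. Adjusted p was 0.0720 for astrocytes (0.00266 without vehicle 2 and 4.88e-05 without EB 4), 0.166 for oligodendrocytes, 0.276 for microglia, where P2ry12 (log2 −0.41) passed over the list alone, 0.920 for oligodendrocyte precursors (downward, with a median of 0.02 and a mean of 0.05) and 0.452 for tanycytes and ependymal cells. It was 0.932 for choroid plexus, 0.897 for pituitary (0.0244 without EB 4; downward, with a mean of 0.06 and a median of −0.01), 0.820 for blood cells, 0.897 for lateral and dorsal hypothalamus, 0.897 for GABAergic neurons, 0.846 for paraventricular, supraoptic and suprachiasmatic nuclei and 0.787 for thalamus, where Slc17a6 passed over the list alone. Genes that vary between B6 and 129 strains gave 0.838 (downward, with a median of 0.00 and a mean of 0.05), and Erdr1 (log2 2.30, adjusted p = 0.139) passed over that list alone. Mitochondrially encoded genes gave 0.897 (0.00915 without vehicle 2), and Xist, the 1 sex-linked gene measured, 0.246. Mixed fry, for change in either direction, gave an adjusted p of 0.00183 for the strain-variable genes and 0.0112 for microglia. For every other list of this paragraph it was 0.29 or more. Whether strain ancestry differed between the groups was not tested.

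**Figure D4:**
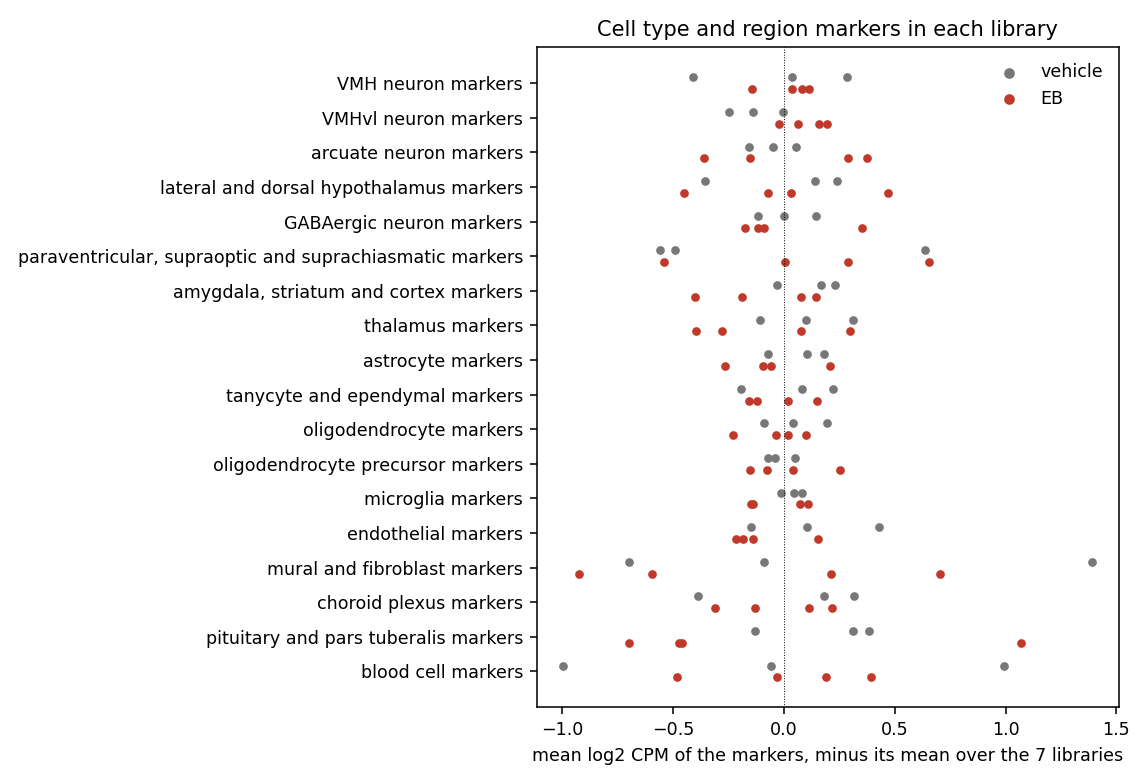
Mean log2 CPM of each list of cell type or region markers in each library, minus its mean over the 7 libraries (grey, vehicle; red, EB). Vehicle 1 lies at 1.39 for mural and fibroblast markers and EB 4 at 1.07 for pituitary markers.

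The libraries differed in mitochondrial ribosomal RNA, which took 26.1%, 9.92% and 7.88% of the counts of vehicle 1 to 3 and 7.27% (EB 4) to 19.8% (EB 1) of those of the EB libraries. The 10 composition measures, among them total counts, genes detected and Xist, gave two-sided exact permutation p-values from 0.2 to 1 over the 35 splits of the libraries, where the smallest possible p is 0.0286. The first principal component (28.0% of variance) set vehicle 2 apart from the other libraries.

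The called genes lie on many chromosomes; positions are from the GENCODE annotation of GRCm38. Pgr spans chromosome 9 from 8899833 to 8968611 on the plus strand, Greb1 chromosome 12 from 16670615 to 16800886 on the minus strand, Zbtb42 chromosome 12 from 112678828 to 112682747 on the plus strand, and Irs2 chromosome 8 from 10984681 to 11008458 on the minus strand. Mc4r spans chromosome 18 from 66857704 to 66860506 on the minus strand, Mc3r chromosome 2 from 172248492 to 172251114 on the plus strand, Iigp1 chromosome 18 from 60376027 to 60392634 on the plus strand, and Mad2l1 chromosome 6 from 66535390 to 66547220 on the plus strand. Exons of Greb1, Irs2, Gadd45a, Chst15, Popdc3, Nr2f1, Dusp1, Cry2, P2ry12, Abcb1a and Agrp overlap exons annotated on the opposite strand, by 9 bases in P2ry12 to 1206 bases in Chst15. The use of strand in counting is not given in the sources used here, so antisense reads could not be separated in those genes. Exons of Agrp also overlap Gm5914 on the same strand by 114 bases, where reads could belong to either gene.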

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

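The comparison of the share of higher genes across scalings (the scalings themselves were planned) and the tests of the fibroblast, endothelial, pituitary, VMH and astrocyte indices as covariates, and of interferon response, dividing cells and reads shared between paralogs were chosen only after the result was seen.

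EdgeR called Zbtb42, Pgr, Irs2 and 172 other genes different between EB and vehicle, more of them higher than lower with EB. With the 7 libraries split into 3 and 4 in 35 ways, only 1 split, the real one, gave as many calls (175 against at most 11 in another split). This argues against a chance split but cannot exclude it, since the smallest possible permutation p over 35 splits is 0.0286. The other splits mix EB and vehicle mice, so any group difference would itself lower their counts. The share of higher genes was 75.3% to 86.7% under 3 other scalings against 78.3%, which argues against scaling as the cause of the excess, but it was 65.2% with DESeq2, 64% with no filter and 58.3% with the endothelial covariate, so its size depends on the test, the filter and the covariate. With any of 6 marker indices as covariate the median change of the called genes was at least 0.76 against 0.77 in the main test. Lower 95% bounds, from resampling called genes and not mice, were 0.698 or more. The indices followed treatment only in part (correlation from −0.50 to 0.18), so adjusting for them could lower the change little. The covariate test therefore cannot decide whether differences in the tissue sampled underlie the calls, and that explanation stays open. A direct or indirect action of estradiol may underlie the set, as a hypothesis, and variants of the mixed strain background remain untested.

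Iigp1 rose 24.9-fold. Gm4951 (log2 3.71) and the pseudogene Gm5970 (4.36), which lies within the span of Gm4951 on the same strand, were chosen after their values were seen and rose from 0 to 8 and 1 to 2 counts in vehicle libraries. The other 31 interferon-stimulated genes had a median log2 change of −0.19 (−0.18 with Iigp1 and Gm4951 included). The upper 95% bound was −0.11 from resampling genes, which leaves out variation between mice. EdgeR, DESeq2 and limma-voom called 0 of the 31, with 3 at an unadjusted p under 0.05. A decrease of the list did not pass either (camera, adjusted p = 0.122, and 0.511 with an estimated correlation). These values argue against a general interferon response. Reads of Iigp1 counted for its paralog Gm4951 stay open: the ratio was 4.24% to 12.3% in the 4 EB libraries, beyond counting error (chi-square p = 2.1e-06), but amplification could add such noise, so the explanations cannot be told apart for Gm4951. Iigp1 lost its call without vehicle 2 (adjusted p = 0.123), Gm4951 without vehicle 1, 2 or 3 (0.128, 0.228 and 0.202) or EB 1, 2 or 3 (0.132, 0.0612 and 0.0756), and Gm5970 without vehicle 1, 2 or 3 (0.157, 0.166 and 0.179). A strain variant near Iigp1 was not tested.

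Mad2l1, a spindle checkpoint gene, rose from 9.25 ± 2.57 to 71.2 ± 13.9 CPM (log2 2.93). The 27 other cell division genes had a median log2 change of 0.25 (0.27 with Mad2l1 included). The upper 95% bound of this median was 0.40, from resampling genes, which leaves out variation between mice. Both lie far under 1.47, which is 50% of the change of Mad2l1. EdgeR, DESeq2 and limma-voom called 0 of the 27, with 4 at an unadjusted p under 0.05. Of the 27, 20 had positive changes, and fry gave an upward direction (adjusted p = 0.0426) where camera did not pass (0.122; adjusted p = 0.233 with an estimated correlation), so a small rise of the list stays open. Its size argues against dividing cells as the whole cause of the change of Mad2l1, and regulation of Mad2l1 itself remains a hypothesis.

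Within the EB group, 6 of 95 values stood apart from the other 3 mice, against 4.75 expected by chance. Gadd45a was at 15.6 CPM in EB 2 and at least 20.9 in the others. Popdc3 was at 1.34 CPM in EB 1 and 2.90 to 3.16 in the others. Oxtr was at 61.9 CPM in EB 4 and 77.6 to 79.9 in the others. Abcb1a was at 18.2 CPM in EB 4 and 11.4 to 11.8 in the others. The GABAergic neuron marker index was 0.35 in EB 3 and −0.18 to −0.09 in the others, and the pituitary marker index 1.07 in EB 4 and −0.70 to −0.46 in the others.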

How the results depend on the processing

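The list tests without each library, the removal of rRNA genes or of vehicle 1 with EB 4, and the fibroblast and endothelial covariates were chosen only after the result was seen. All 175 changed genes kept their direction in each alternative that tested them. The 2 groups did not overlap in any of these genes, so a kept direction says little about stability. Of the 175, 83 were called without each library in turn, and 67 under all 26 alternatives. Counts of changed, higher and lower genes were 359, 234 and 125 with DESeq2 (170 shared with the 175), 375, 240 and 135 with no filter (172 shared), and 85, 73 and 12 against a 1.2-fold change. Lower genes numbered 17 with library totals, 64 at an adjusted p under 0.1 and 69 with the fibroblast covariate, and the endothelial covariate gave 264 changed and 110 lower. Leaving out 1 library gave 102 to 152 changed, 78 to 122 higher and 20 to 45 lower genes; the lowest counts were without vehicle 3 (102, 78 and 24) and EB 1 (107, 87 and 20), and EB 2 gave 24 lower. Of 1375 named-gene alternatives 1234 kept direction and call, 98 lost and 40 gained a call, and 3 changed sign: Esr1 with a surrogate variable (0.027) and without vehicle 2 (0.13), with a range of −0.38 to 0.13 without 1 library, and Esr2 without vehicle 2 (0.040), with a range of −0.60 to 0.040. The cause was not tested. With an estimated correlation the adjusted p was 0.159 for estrogen receptor targets, 0.341 for immediate early genes, 0.723 for glutamate and GABA receptors, and 0.709 for the VMHvl, energy and insulin, endothelial, and amygdala, striatum and cortex lists. By fry it was 0.0364 for estrogen receptor targets, 0.150 for immediate early genes and 0.542 for the other 5. Mixed fry gave 0.00104 for melanocortin, 1.8e-05 for neuropeptide receptors, 5.0e-06 for steroid receptors and 0.00141 for clock genes. It missed the threshold for glucocorticoid response genes (0.0568) and neuropeptides (0.180). Without 1 library the adjusted p of the list test ranged from 0.000136 to 0.0143 for estrogen receptor targets, 1.25e-07 to 0.00238 for immediate early genes, 5.41e-05 to 0.330 for endothelial markers, 0.000445 to 0.0716 for glutamate and GABA receptors, 0.00915 to 0.197 for energy and insulin, 0.000536 to 0.589 for VMHvl, and 0.00316 to 0.258 for amygdala, striatum and cortex. It ranged from 4.88e-05 to 0.557 for astrocytes, 0.000251 to 0.522 for mural cells and fibroblasts, 0.00915 to 0.976 for mitochondrial genes, 0.0184 to 0.522 for melanocortin, 0.0184 to 0.375 for neuropeptide receptors, 0.0244 to 0.998 for pituitary and 0.0496 to 0.697 for steroid receptors. No paired analysis was possible because the labels give no shared replicate numbers. At this depth 6 changed genes had under 10 counts on average in a group, among them Zbtb42 and Arhgef38, so their folds are imprecise.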

Other observations

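The 8 added lists and their genes were chosen after their values were seen, and so was the test of synaptic genes. Adjusted p-values of their list tests are over these 8 lists only.

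Signalling genes outside the report's lists also changed. Trpc7 and Trpc4, cation channels opened downstream of G-protein-coupled receptors, rose from 22.9 ± 3.38 to 51.0 ± 7.02 CPM (log2 1.16 ± 0.13) and from 41.9 ± 4.43 to 75.1 ± 8.31 CPM (0.84 ± 0.11), so 2 of 6 measured TRPC genes were higher, and 3 when adjusted over the list alone (camera, adjusted p = 8.99e-07; adjusted p = 0.0228 with an estimated correlation). Rgs4, Rgs2 and Rgs19, which speed the turn-off of G proteins, rose from 49.7 ± 4.33 to 107 ± 13.5 CPM, 187 ± 27.3 to 321 ± 45.0 CPM and 28.8 ± 1.07 to 41.9 ± 2.42 CPM, 3 of 18 RGS genes, against 3 higher and 2 lower when adjusted over the list alone (camera, adjusted p = 0.125; adjusted p = 0.233 with an estimated correlation). Htr1a and Adra2a were the 2 called of 30 aminergic receptors, both lower, against 1 higher and 4 lower when adjusted over the list alone (camera, adjusted p = 0.00377; adjusted p = 0.233 with an estimated correlation). Rgs19 lost its call without vehicle 3 (adjusted p = 0.0761). The TRPC, RGS and aminergic receptor lists were chosen with these calls known and contain the called genes. Their set tests therefore give no independent support for a change of the whole list.

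Enzymes that modify glycans changed in both directions. St3gal1, a sialyltransferase, rose by 1.00 ± 0.15 on the log2 scale and Ndst3, a heparan sulphate sulphotransferase, by 0.77 ± 0.12, together with Chst15, Mgat1, Chst1 and Ext1. The polysialyltransferase St8sia4 fell from 89.7 ± 5.95 to 52.7 ± 4.97 CPM and St8sia6 from 28.5 ± 2.14 to 16.9 ± 0.843 CPM. Of 48 measured 6 were higher and 2 lower, against 8 and 5 when adjusted over the list alone, and the set test was downward with a median of −0.03 and a mean of 0.03 (camera, adjusted p = 0.855; adjusted p = 0.876 with an estimated correlation). Dhcr7 (log2 0.88 ± 0.11), the enzyme of the last step of cholesterol synthesis, was the 1 called of 22 genes of that pathway, also when adjusted over the list alone (camera, adjusted p = 0.122; adjusted p = 0.511 with an estimated correlation). Higher glycan enzyme genes numbered 2 without vehicle 2 and 3 without vehicle 3, EB 1 or EB 2. Chst15 lost its call without vehicle 2 or 3 (adjusted p = 0.169 and 0.133), Mgat1 without vehicle 2, EB 1 or EB 2 (0.0653, 0.0828 and 0.0743), Chst1 without vehicle 1, 2 or 3 or EB 1 or 2 (0.0511, 0.0639, 0.0668, 0.0862 and 0.0552), and Ext1 without vehicle 2 or 3 or EB 1, 2 or 4 (0.105, 0.148, 0.112, 0.0743 and 0.0852).

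Genes of synaptic adhesion and axon guidance had mostly negative changes. Slitrk4 fell from 242 ± 28.7 to 146 ± 16.5 CPM, Unc5c by 0.51 and Pcdh20 by 0.65 on the log2 scale, while Sema6a (0.62) and Igsf3 (1.00) rose. Of 69 measured, 3 were higher and 7 lower, against 5 and 12 when adjusted over the list alone, and 48 had negative changes (camera, adjusted p = 2.53e-05; adjusted p = 0.174 and unadjusted p = 0.0435 with an estimated correlation). Fry gave a downward direction for the list (adjusted p = 0.0426). The 59 members not called had a median log2 change of −0.07, with 41 negative (camera with an estimated correlation, unadjusted p = 0.0828). The calls themselves decided that split, so it cannot settle whether the rest of the list fell. The list was drawn up from called genes, so a decrease of the whole set may exist but cannot be told apart from the changes of those genes. Leaving out 1 library gave 3 lower genes without vehicle 3, 4 without vehicle 2 or any of EB 1 to 4, and 7 without vehicle 1, and 2 higher genes without each of the 7 in turn. Igsf3 lost its call without vehicle 3 (adjusted p = 0.0565), while Slitrk4, Unc5c, Pcdh20 and Sema6a were called without each library in turn.

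Called genes lay near each other on the chromosomes. Greb1 and E2f6 lie 10076 bases apart, Phf21b and Nup50 67361, and Iigp1 and Smim3 81556, and each pair rose. Zbtb42 and Kif26a, which also rose, lie 497080 bases apart. Of 174 called genes with a position, 33 had another called gene within 500 kb that changed in the same direction, against a median of 17 and a 95th percentile of 26 in 10000 random sets matched on expression (permutation p = 0.0037). Counting only neighbours at least 20 kb apart gave 26 genes against a 95th percentile of 24 (permutation p = 0.025). Shared regulatory elements may underlie these pairs, which remains a hypothesis, since the read overlap of close pairs such as Pgr and Gm16485, 3179 bases apart on the same strand, or Gm5970 within Gm4951, which count as separate genes among the 33, and linked strain variants were not tested. Without 1 library E2f6 lost its call (vehicle 3, adjusted p = 0.0774; EB 1, 0.0537), and so did Nup50 (vehicle 1, 0.0522; EB 1, 0.0527) and Iigp1 (vehicle 2, 0.123).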
